A study of Homo sapiens with 6 samples.

How the data were processed

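The study compared untreated MCF7 cells with cells treated with paclitaxel for 8 h and 48 h, with 2 arrays per group and 6 arrays in all. Per the labels, total RNA of the cells was labelled with Cy5 and a universal human reference RNA with Cy3, and both were hybridised to a 2-colour cDNA clone array. The labels state neither the dose of paclitaxel nor the time at which the untreated cells were taken, nor whether the A and B samples came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

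The values are the log ratios deposited by the authors, read here as log2. The normalization, background correction, spot filter and software were not given in the sources used here, and neither was a genome build, so no coordinates are printed. The array medians differed by 0.172 at most, under the tolerance of 0.2 set before the data were examined, so the values were used as deposited without centring. The medians were -0.01 and 0.16 for control A and B, 0.01 and 0.003 for 8 h A and B, and 0.02 and 0.08 for 48 h A and B. The log base and the direction of the ratio are not stated with the values. The lowest value was -7.32, a ratio that in base 10 would exceed the range of a 16-bit scanner, so base 2 was used. The lowest values of 8 h B (-5.05889) and 48 h B (-5.71786) are base 2 logarithms of short decimal ratios. This argues against natural logarithms on these arrays, and on the others natural logarithms are not excluded. The direction was taken as Cy5 over Cy3 from the labels and checked with marker lists, since the luminal markers lay above the markers of other lines by 2.02 to 3.10 on the 4 paclitaxel arrays. No array correlated with another below r = -0.05, and the lowest rho was -0.11, between control B and 48 h B. Background-level signal per spot was not analysed here, and blank cells were treated as missing.

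Of 13056 rows, 8047 had 1 gene symbol in the platform annotation, 276 had several and 4733 had none. Only rows with 1 symbol were named. Of these, 8035 matched a gene of the RefSeq table (assembly GRCh38.p14) by Entrez gene ID, which changed no symbol, and 12 kept the annotation's name. Rows of the same gene were averaged on the log2 scale, which gave 4325 genes, of which 2731 had a value on all 6 arrays and were tested. Of these, 1578 had several rows, and in 433 (27.4%) the changes of single rows at 48 h against control lay over 1 apart on the log2 scale. Rows named for pseudogenes (HSPB1P2, HSP90B2P) and cDNA clones of tubulins, histones and other families can bind transcripts of near-identical genes, so their gene assignment is uncertain.

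Group means were fitted over all 6 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 24 gene lists, all fixed before the data were examined, were p53 targets, mitosis, DNA replication, histones, tubulins, microtubule-associated proteins, estrogen response, interferon response, NF-kB and cytokines, immediate early genes, ER stress, heat shock proteins, apoptosis, lysosome and autophagy, ribosomal proteins, oxidative phosphorylation, glycolysis, sterol and fatty acid synthesis, drug transport and metabolism, matrix and adhesion, DNA repair, proteasome, luminal breast markers and markers of other lines in the reference. The 23 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The histone list had 4 measured members and was not tested.

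The rule for naming genes was fixed in advance. For each comparison with control it took the 10 largest rises and 10 largest falls among genes past the threshold whose treated arrays both lay on the same side of both control arrays, filled to 5 per direction by smallest p where fewer passed. For 48 h against 8 h it took 5 and 5, filled to 3. Up to 4 members of each list with the smallest p at 48 h against control could be named, and CDKN1A, MDM2, CCNB1, CDC20, PLK1, AURKA, TOP2A, MKI67, BIRC5, TUBB, TUBA1B, ESR1, TFF1, PGR, CCND1, BCL2, MYC and PCNA always. CCNB1, CDC20, TUBA1B and ESR1 had no named row, and PGR had values on some arrays only. Other genes named, including further list members in the comparison of 48 h with 8 h, were chosen after their values were seen. The genes with the largest change common to both batches were ranked by the smaller of their 2 batch changes, which replaced a first ranking by the change in the block fit.

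Alternatives fixed in advance were centring on array medians, quantile normalization, testing each row, the median over rows, genes with at least 1 array per group, only the 2 groups compared, robust eBayes, the letter as a block, other thresholds and leaving out each array. Added after seeing the data were the batch read from the pattern of blank cells as a block, the letter as a block with only 2 groups in the fit, scale normalization, array weights, and the list tests with an estimated correlation and with fry in the block fit. The tests were checked on simulated data with 200 of 2731 genes changed. For 48 h against 8 h, log2 changes of 1, 2 and 3 were recovered in 5.97%, 62.7% and 95.5% of genes, with 5 false calls, and for 48 h against control in 11.9%, 62.7% and 93.9%, with 4. For 8 h against control the shares were 7.46%, 58.2% and 97.0%, with 4 false calls. With the 4 paclitaxel arrays and a block they were 53.7%, 100% and 100%, with 2. A shift of -0.5 given to the mitosis list was found by camera in 50 of 50 simulations, with 0 calls among 200 tests of other lists. The simulated genes varied independently, so this does not show how often camera calls lists of genes that vary together.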

Results

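Gene expression was measured in MCF7 cells, an estrogen receptor-positive line from a human breast cancer, without treatment and after 8 h and 48 h of paclitaxel, a drug that binds and stabilises microtubules. There were 6 two-colour cDNA arrays, 2 per group, named A and B in each group. On each array RNA from the cells carried Cy5 and a common reference, RNA pooled from several human cell lines, carried Cy3. Each value is a log ratio of cells to reference, read as log2. A change is a difference between 2 group means of log2 ratios, given ± its standard error from limma, with n = 2 arrays per group throughout. The base of the logarithm is not stated with the values, and with natural logarithms each fold would be larger than printed. The table has 13056 rows, of which 8354 and 8698 carried a value on control arrays A and B, 12269 and 9637 on the 8 h arrays, and 12098 and 9565 on the 48 h arrays. All comparisons used the 2731 named genes with a value on all 6 arrays. The small number of arrays limits the precision.

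Control A did not share the profile of the paclitaxel arrays, and control B shared it at most in part. This bears on every change drawn from the control arrays. TFF1, an estrogen-induced secreted protein typical of MCF7 cells, had log2 ratios of 2.51 and 3.36 on the 8 h arrays and 2.48 and 3.48 on the 48 h arrays, against -0.19 and -0.51 on control arrays A and B. EPCAM, an epithelial adhesion protein, stood at 2.78 to 3.68 on the paclitaxel arrays, at 1.93 on control B and at -0.05 on control A. SPARC, a matrix protein of mesenchymal cells, stood at -7.19 to -5.06 on the paclitaxel arrays. It stood at -3.73 on control B and at -0.63 on control A. Its value on 8 h B is the lowest of that array (-5.05889), so the size of its differences there is uncertain. The median of the luminal breast markers minus the median of the markers of other lines in the reference was 2.02 and 2.84 at 8 h, 2.14 and 3.10 at 48 h, 1.04 on control B and 0.0056 on control A. The standard deviation of the log2 ratios over genes was 0.26 on control A, 0.73 on control B and 0.72 to 1.12 on the paclitaxel arrays.

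**Figure D1:**
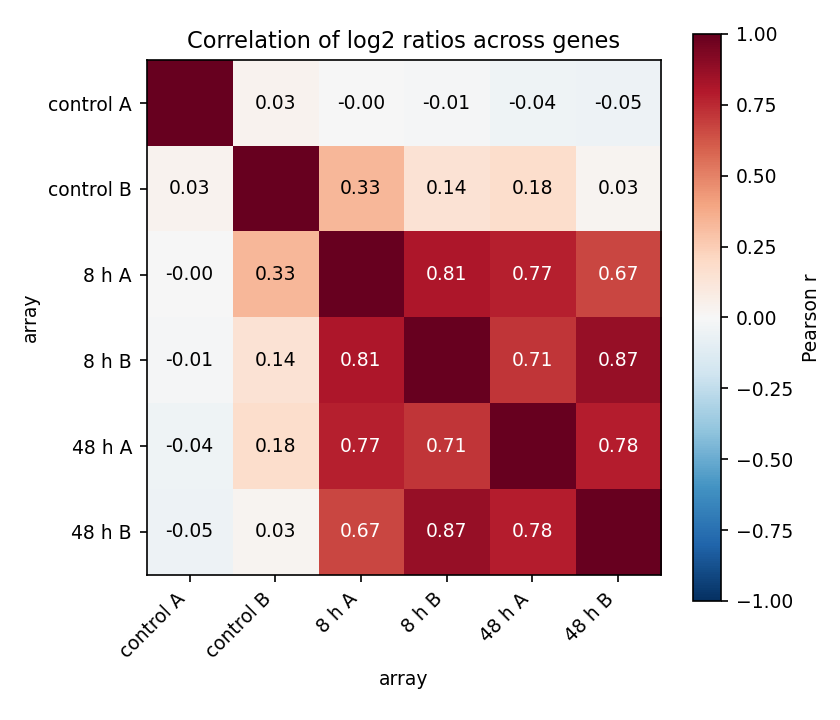
Pearson correlation of log2 ratios across 2731 genes for every pair of the 6 arrays, with one cell of the grid per pair (both axes list the arrays, and the colour scale runs from -1 to 1). The 4 paclitaxel arrays correlate at 0.67 to 0.87 with each other, and control A stays between -0.05 and 0.03 with every other array.

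Across genes, which are not independent replicates, the 8 h arrays correlated with each other at r = 0.81 (Spearman's rho 0.72) and the 48 h arrays at r = 0.78 (rho 0.73), whereas the arrays labelled control correlated at r = 0.03 (rho 0.02). Control B correlated at 0.33 with 8 h A, 0.14 with 8 h B, 0.18 with 48 h A and 0.03 with 48 h B. In the same order rho was 0.20, -0.02, 0.05 and -0.11, so by rank control B shared little of the profile. Clones present more than once on an array gave log2 ratios that correlated at 0.80 on control B and at 0.39 on control A, against 0.67 to 0.92 on the paclitaxel arrays. The blank cells of the table fell into batches. Whether a cell was blank correlated at 0.80 to 0.92 among control B, 8 h B and 48 h B, at 0.53 between 8 h A and 48 h A, and at 0.23 or less between control A and any other array. Values within these batches are therefore given beside the pooled ones for the gene lists that passed and the largest gene changes. The batch of A arrays holds 8 h and 48 h, the batch of B arrays holds all groups, and control A stands alone. CD69 stood at base 2 logarithms of short decimal ratios on 8 h B (-0.96578) and 48 h B (-2.4189), but not on control B (0.80925). Control B may therefore have been processed differently from the other B arrays, which limits its comparison within the batch.

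The comparison of 48 h with 8 h asked how expression differed between early and prolonged exposure, and it does not use the arrays labelled control as a baseline. Its standard errors and p-values come from the fit of all 6 arrays, so they include the difference between the control arrays. For TUBB (± 0.81) the control arrays stood at -0.11 and -3.06, and the paclitaxel arrays from -0.07 to 0.85. With only the 2 groups fitted, 0 genes and 3 lists passed. By camera at its preset correlation, genes induced by p53 rose as a group from 8 h to 48 h. By the same test, genes of DNA replication and of mitosis fell as groups. None of these lists passed at an estimated correlation (camera adjusted p = 0.873 for each). The latter test had few residual degrees of freedom and passed no list in any comparison, so its outcome decides little. CDKN1A (Entrez gene 1026), the p21 inhibitor of cyclin-dependent kinases, was 3.80-fold higher at 48 h (log2 change 1.93 ± 0.40). TP53INP1, a stress-induced p53 target, was 5.6-fold higher (2.49 ± 0.44). TOP2A, the DNA topoisomerase of proliferating cells, stood 2.95-fold lower (-1.56 ± 0.53), and PCNA, the sliding clamp of DNA polymerases, 2.62-fold lower (-1.39 ± 0.69). No single gene passed the test in this comparison (smallest limma adjusted p = 0.786), so these gene values carry no call. At an unadjusted p under 0.05 there were 133 genes, 68 higher and 65 lower.

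**Figure D2:**
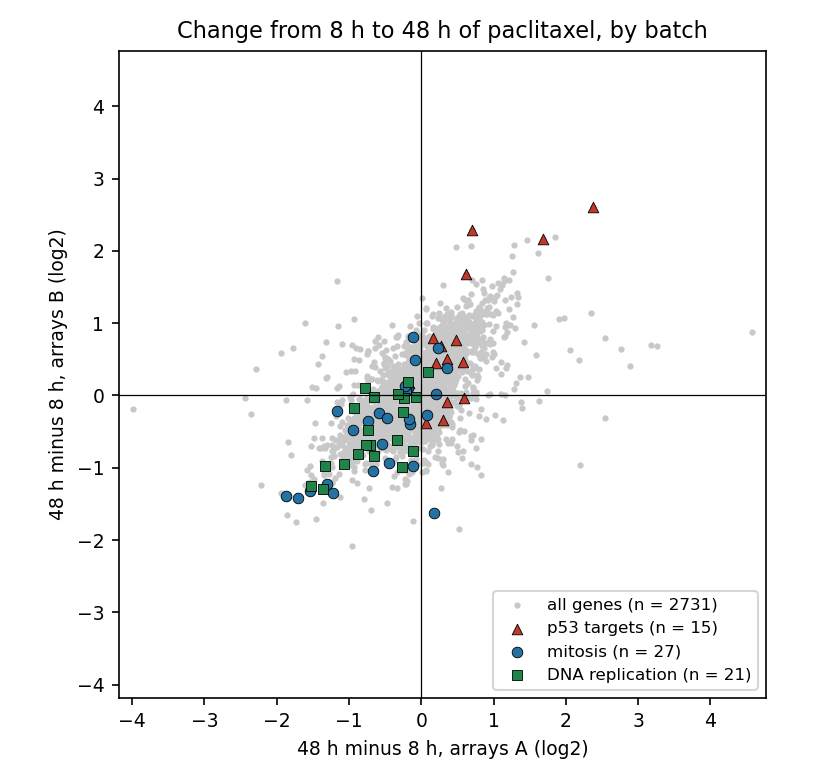
Change in log2 ratio from 8 h to 48 h of paclitaxel, on the A arrays (horizontal axis) and the B arrays (vertical axis), for each of 2731 genes, with the members of 3 gene lists marked. The p53 targets lie mostly above 0 on both axes (list medians 0.36 on A and 0.51 on B), and the DNA replication genes mostly below 0 on both (-0.66 and -0.61).

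Of the 15 measured p53 targets, 13 were higher at 48 h, with a median change of 0.48 (camera adjusted p = 0.000673; 0 members passed over all genes tested and 2 adjusted over the list alone). The median was 0.36 within the A arrays and 0.51 within the B arrays. FAS, a death receptor, changed by 0.69 on A and 2.29 on B. BBC3, the PUMA protein that promotes apoptosis, changed by 0.62 and 1.68, and MDM2, the ubiquitin ligase that limits p53, by 0.57 and 0.46. Of the 21 DNA replication genes, 19 were lower, with a median of -0.55 (camera adjusted p = 2.61e-05) and medians of -0.66 on A and -0.61 on B. CDC45, part of the replicative helicase, changed by -1.36 and -1.29, PRIM2, a primase subunit, by -1.33 and -0.98, and TK1, thymidine kinase, by -1.06 and -0.95. Of the 27 mitosis genes, 22 were lower, with a median of -0.42 (camera adjusted p = 8.95e-05) and medians of -0.22 on A and -0.32 on B. The kinetochore gene NDC80 changed by -1.87 and -1.39, the mitotic kinase CDK1 by -1.54 and -1.33, and the phosphatase CDC25C by -1.22 and -1.35. AURKA changed by -0.18 and 0.10 and PLK1 by -0.12 and 0.80, with opposite signs in the batches, and MKI67 by -0.17 and -0.32. In the DNA replication and mitosis lists, 0 members passed over all genes tested and 0 adjusted over the list alone. None of the 3 list calls held with fry either (adjusted p from 0.509 to 0.860).

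With the batch as a block, a fit chosen after seeing the data, 454 genes passed, 252 higher and 202 lower at 48 h, and 449 of them had the same sign in both batches, which their selection on the mean change favours. Over all 2731 genes the sign was the same in 73.2%. That fit had 1 residual degree of freedom and used a single spread (SD 0.258) for every gene, so its p-values rest on that shared spread. In it the 3 lists had camera adjusted p = 7.07e-05 for p53 targets, 1.13e-05 for DNA replication and 1.65e-05 for mitosis, and none held with an estimated correlation (adjusted p = 0.936 for each) or with fry (0.309 to 0.326). With 1 residual degree of freedom hardly any list could pass these last tests, so that outcome decides little. Members of the 3 lists past the threshold were 4 higher p53 targets, 8 lower DNA replication genes and 10 lower mitosis genes. Over all genes, 30 were higher by at least 1 in both batches and 31 were lower by at least 1 in both, against 1 that moved by at least 1 in opposite directions and 325 that moved by at least 1 in either batch. At a change of 0.5, 258 were higher in both, 212 lower in both and 37 opposite.

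The genes with the largest change common to both batches were chosen after their values were seen. The higher ones were TP53INP1 (2.37 on A and 2.60 on B), the histone gene H2BC21 (1.86 and 2.19), CDKN1A (1.68 and 2.17), TMEM248 (1.75 and 1.63) and the histone gene H4C8 (1.62 and 1.97). The 12 rows of H2BC21 had changes from 0.27 to 3.40. The lower ones were CAPG, an actin-capping protein (-1.74 and -1.75), LYZ, lysozyme (-1.86 and -1.65), CCN2, a matricellular growth factor (-1.46 and -1.71), CD69, a membrane receptor (-1.71 and -1.45) and DLK1 (-1.71 and -1.43). The smallest p-values of the main test belonged to TP53INP1, H2BC21 and CDKN1A among higher genes and to FBXO5, COL11A2 and CD69 among lower ones. FBXO5, an inhibitor of the anaphase-promoting complex, changed by -1.94 on A and -1.35 on B. COL11A2, a collagen chain, changed by -1.84 and -1.43. Among the other genes listed in advance, CCND1, cyclin D1, changed by 1.32 ± 0.47 (1.11 on A and 1.52 on B), MYC by 0.39 ± 0.41, BCL2 by 0.23 ± 0.42, BIRC5 by -0.42 ± 0.66, TUBB by 0.18 ± 0.81 and TFF1 by 0.05 ± 0.47.

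**Figure D3:**
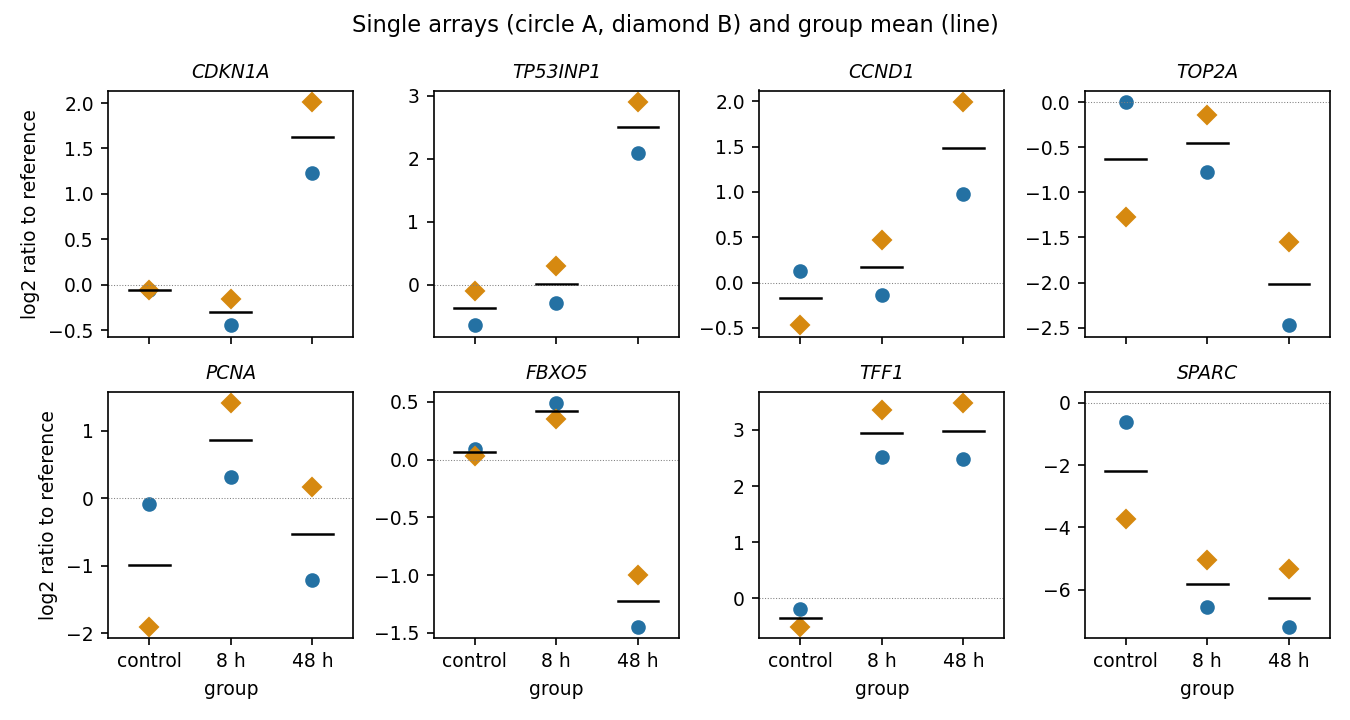
Log2 ratio to the reference (vertical axis) of 8 genes on each array, by group (horizontal axis), with circles for A arrays, diamonds for B arrays and a line at the mean of the 2 arrays. CDKN1A and TP53INP1 are higher at 48 h than at 8 h on both arrays (CDKN1A 1.23 and 2.01 against -0.45 and -0.16), and SPARC is at -0.63 on control A and -3.73 on control B.

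The other 20 tested lists did not pass between 8 h and 48 h (camera adjusted p from 0.0850 to 0.819). The medians of 11 of these lists turned sign under at least 1 other scaling. Over all genes the median change was 0.07. Medians were 0.46 for immediate early genes, 0.42 for glycolysis, 0.41 for apoptosis, 0.35 for sterol and fatty acid synthesis, 0.34 for microtubule-associated proteins, 0.31 for ER stress, 0.31 for heat shock proteins and 0.28 for the interferon response. They were 0.23 for the estrogen response, 0.21 for oxidative phosphorylation, 0.20 for DNA repair, 0.19 for the proteasome, 0.12 for luminal breast markers, 0.07 for NF-kB and cytokines and 0.05 for tubulins. Below 0 were lysosome and autophagy (-0.01), drug transport and metabolism (-0.06), ribosomal proteins (-0.06), matrix and adhesion (-0.09) and markers of other lines in the reference (-0.21). Ribosomal proteins passed with quantile and scale normalization (medians -0.30 and -0.31, camera adjusted p = 0.00324 and 0.00102). So did glycolysis (0.41 and 0.35, camera adjusted p = 0.0334 and 0.0151) and immediate early genes (0.38 and 0.35, camera adjusted p = 0.0133 and 0.00401). Within the batches, 5 of the 20 had medians of opposite sign, namely tubulins (-0.14 on A and 0.28 on B), luminal breast markers (-0.03 and 0.12), lysosome and autophagy (-0.07 and 0.15), ribosomal proteins (-0.14 and 0.01) and NF-kB and cytokines (-0.01 and 0.02). For tubulins and for NF-kB and cytokines the camera statistic was below 0 while mean and median were above it. For lysosome and autophagy, and for drug transport and metabolism, mean and median had opposite signs.

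The comparison of 48 h of paclitaxel with no treatment gave the most calls with the test fixed in advance, and all its directions are drawn from the arrays labelled control. With limma, 220 of 2731 genes passed, 95 higher and 125 lower at 48 h. The largest rises that passed were in HSPB1P2, STARD10, a lipid transfer protein, IL1RN, the interleukin 1 receptor antagonist, TFF1, UBL3, ATP5MF, a subunit of ATP synthase, TUBA1A, an alpha-tubulin, GSTM3, a glutathione transferase, TP53INP1 and TOB1, an antiproliferative protein. Their log2 changes ran from 2.83 ± 0.51 in TOB1 to 3.62 ± 0.47 in HSPB1P2. STARD10 rose by 3.54 ± 0.36 (limma adjusted p = 0.0123), TFF1 by 3.33 ± 0.47 (adjusted p = 0.0151) and TP53INP1 by 2.86 ± 0.44 (adjusted p = 0.0151). The largest falls were in GPC3, a glypican, SPARC, CCN2, THBS2, a thrombospondin, ANXA1, annexin A1, CD69, SPP1, osteopontin, TNFRSF11B, osteoprotegerin, IQGAP2 and the cancer-testis antigen MAGEA1, from -2.88 ± 0.57 in MAGEA1 to -4.22 ± 0.91 in GPC3. CCN2 fell by 4.07 ± 0.52 (adjusted p = 0.0146) and CD69 by 3.28 ± 0.37 (adjusted p = 0.0133). CDKN1A rose by 1.68 ± 0.40 (adjusted p = 0.0418) and AURKA, the Aurora A kinase, by 1.78 ± 0.41 (adjusted p = 0.0388).

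By camera at its preset correlation 7 lists passed at 48 h, and none of them with an estimated correlation (adjusted p = 0.920 for each). The luminal breast markers rose (8 of 9 positive, median 1.15, camera adjusted p = 0.0153) and the markers of other lines in the reference fell (15 of 19 negative, median -1.14, camera adjusted p = 0.000776), both relative to the arrays labelled control. Among the latter the fibroblast gene LUM fell by 2.59 ± 0.47, LYZ by 2.23 ± 0.45 and the melanocyte gene MLANA by 2.69 ± 0.62. These cell identity markers moved together with the gene groups that follow. The matrix and adhesion list shares VIM, SPARC, COL1A1, COL1A2 and COL3A1 with the markers of other lines, so these lists are not independent. SPARC, which passed, counts in both. Matrix and adhesion genes fell (15 of 21 negative, median -0.74, camera adjusted p = 0.00533), among them CDH2, N-cadherin, by 2.15 ± 0.36 and ITGA6, an integrin, by 1.87 ± 0.43. NF-kB and cytokine genes fell (11 of 18 negative, median -0.13, camera adjusted p = 0.0478), among them PLAU, urokinase, by 2.42 ± 0.37 and the chemokines CCL20, CXCL3 and CXCL1. The NF-kB and cytokines call also ended on centring (median -0.11, camera adjusted p = 0.0528), with quantile (-0.32, 0.0709) or scale normalization (-0.29, 0.0873) and without 48 h B (-0.41, 0.112), so its median was larger in size in 3 of these 4 fits. Heat shock proteins rose (13 of 13 positive, median 1.17, camera adjusted p = 0.00213), as did oxidative phosphorylation (19 of 22 positive, median 1.21, camera adjusted p = 0.00169) and the proteasome (15 of 16 positive, median 1.2, camera adjusted p = 0.00225). Examples were STIP1, a co-chaperone, at 2.18 ± 0.54, COX17, which carries copper to cytochrome oxidase, at 2.12 ± 0.42, and the proteasome subunit PSMD12 at 2.19 ± 0.48.

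Members past the threshold over all genes tested were 2 of the luminal markers, 7 of the markers of other lines, 4 of matrix and adhesion, 4 of NF-kB and cytokines, 1 of the heat shock proteins, 3 of oxidative phosphorylation and 2 of the proteasome. Adjusted over the list alone, they were 3, 9, 9, 5, 4, 7 and 7. The other 16 lists did not pass (camera adjusted p from 0.108 to 0.910). The tubulins had a median of 1.46 (9 of 11 positive, camera adjusted p = 0.108) and passed with each row tested (0.00019) and with only the 2 groups fitted or without either 8 h array (0.00147). The p53 targets had a median of 0.51 (11 of 15 positive, camera adjusted p = 0.202). In the mitosis list 19 of 27 were positive (median 0.28, camera adjusted p = 0.910), and in DNA replication 13 of 21 (median 0.47, camera adjusted p = 0.673). Within the B arrays the medians of these 4 lists were 3.09, 0.83, 0.83 and 1.2. The median over all genes was 0.21 in the pooled fit and is not given here within the B arrays. A list median above 0 is therefore not by itself a rise relative to other genes. Members that passed in the lists without a call were, upward, the p53 targets TP53INP1 and CDKN1A, AURKA of mitosis, TUBA1A of the tubulins, TFF1 of the estrogen response, the interferon-induced genes IFI30 (2.74 ± 0.42) and UBE2L6 (1.38 ± 0.36), the tubulin cofactor TBCC (1.52 ± 0.39), the transporter ABCC5 (2.39 ± 0.41), GSTM3 and the DNA repair gene RAD51C (2.56 ± 0.41). Downward they were the microtubule-associated protein MAP1B (-2.61 ± 0.40), the glutathione transferase GSTP1 (-1.74 ± 0.35), the cathepsin CTSS (-2.12 ± 0.53), the BCL2 family gene BID (-2.19 ± 0.50) and CCN2 of the immediate early genes. In the histone list, which was not tested, H4C8 (2.82 ± 0.55) and H2BC21 (1.95 ± 0.39) passed upward.

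The count at 48 h depended on single arrays and on the scaling. With quantile normalization 17 genes passed, with scale normalization 0 and with array weights 27, the last 2 chosen after seeing the data. Without control A 0 genes passed and without control B 40, without 48 h A 470 and without 48 h B 61, and without either 8 h array 349. The balance of higher and lower genes turned as well, with 336 higher and 134 lower without 48 h A, 196 and 153 without either 8 h array and 1026 and 582 with the batch as a block. Without control A the calls of luminal markers (camera adjusted p = 0.0911), matrix and adhesion (0.0622) and NF-kB and cytokines (median -0.36, 0.0972) ended, and the tubulins (0.00312) and glycolysis (0.0268) passed. The call of luminal markers also ended with scale normalization (0.0873). Within the B arrays, which hold 1 control, all 220 genes had the same sign. Their selection favours this, because the mean change that they were called on includes the B arrays. The named rises were there IL1RN 5.40, TUBA1A 4.84, TFF1 3.99, STARD10 3.72, HSPB1P2 3.64, ATP5MF 3.50, TOB1 3.11, UBL3 3.01, TP53INP1 3.0, GSTM3 2.78, AURKA 2.34 and CDKN1A 2.07. The 10 largest falls had another order and were all smaller than the pooled ones, with CD69 at -3.23, CCN2 at -3.15, IQGAP2 at -2.67, ANXA1 at -2.64, THBS2 at -2.19, GPC3 at -2.03, SPP1 at -1.81, SPARC at -1.59, TNFRSF11B at -1.58 and MAGEA1 at -1.57. The list medians were 1.49 for luminal markers, -0.80 for markers of other lines, -0.55 for matrix and adhesion, -0.12 for NF-kB and cytokines, 1.99 for heat shock proteins, 1.74 for oxidative phosphorylation and 1.84 for the proteasome. The fit with the batch as a block leaves control B as the only baseline, and its spread comes from the paclitaxel arrays alone. Its counts and p-values therefore hold no difference between control arrays, and for lists only medians are given. They were -0.39 for matrix and adhesion, -0.20 for NF-kB and cytokines, 3.05 for the tubulins and 1.855 for glycolysis.

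The comparison of 8 h of paclitaxel with no treatment called no gene with limma (smallest adjusted p = 0.0684), and 429 genes had an unadjusted p under 0.05. TFF1 stood at a log2 change of 3.28 ± 0.47, UBL3 at 2.92 ± 0.43, HSPB1P2 at 2.85 ± 0.47, DNPH1 at 2.37 ± 0.38 and STARD10 at 2.18 ± 0.36. VEGFC, a lymphatic growth factor, stood at -2.50 ± 0.35, IQGAP2 at -2.49 ± 0.38, PTGS1, cyclooxygenase 1, at -2.25 ± 0.37, CCL20 at -2.19 ± 0.40 and CTHRC1 at -1.91 ± 0.35. The rows of CCL20 ran from -3.65 to -1.03. CDKN1A was at -0.24 ± 0.40, AURKA at 1.82 ± 0.41 and PCNA at 1.86 ± 0.69, none of them past the threshold. Within the B arrays TFF1 was at 3.87, HSPB1P2 at 2.91, UBL3 at 2.88, DNPH1 at 2.63, STARD10 at 2.35, VEGFC at -2.39, IQGAP2 at -2.25, PTGS1 at -1.86, CTHRC1 at -1.83, CCL20 at -1.70, CDKN1A at -0.10, AURKA at 2.24 and PCNA at 3.32.

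At 8 h 11 lists passed by camera at its preset correlation, none of them with an estimated one (adjusted p = 0.702 for each), again relative to the arrays labelled control and beside the same shift of cell identity markers (luminal markers median 1.02, camera adjusted p = 0.00329, and markers of other lines median -0.89, camera adjusted p = 0.000499). By the same test genes of DNA replication rose, though not at the estimated correlation (20 of 21 positive, median 0.79, camera adjusted p = 0.000499), as did mitosis (23 of 27 positive, median 0.74, camera adjusted p = 0.00214) and the tubulins (10 of 11 positive, median 1.44, camera adjusted p = 0.00338). Medians were 0.86 for heat shock proteins, 0.85 for ribosomal proteins, 0.97 for oxidative phosphorylation and 0.90 for the proteasome (camera adjusted p from 0.000499 to 0.00214). Matrix and adhesion had a median of -0.50 and NF-kB and cytokines of -0.39 (camera adjusted p = 0.00233 and 0.00214). Adjusted over the list alone, 3 genes of oxidative phosphorylation, 3 luminal markers, 1 mitosis gene, 1 ribosomal protein gene and 1 proteasome gene passed upward, and 6 markers of other lines, 6 matrix and adhesion genes and 4 NF-kB and cytokine genes downward. Over all genes tested 0 members passed. The median change over all genes was 0.10. The other 12 lists did not pass (camera adjusted p from 0.0616 to 0.984), among them the p53 targets (7 of 15 positive, median -0.24, camera adjusted p = 0.588), whose median turned sign with quantile normalization (0.10), scale normalization (0.04), each row tested (0.05) and the batch as a block (0.02).

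Without control B the tubulin call (median 0.38, camera adjusted p = 0.30) and the mitosis call (0.44, 0.0763) ended, and the DNA replication median was 0.46. Without control A these medians were 2.49, 1.2 and 1.18. The tubulins had a median log2 ratio of -2.08 on control B and -0.03 on control A. Without control A the calls of ribosomal proteins, matrix and adhesion, luminal markers and markers of other lines ended (camera adjusted p from 0.0654 to 0.0890). Without 8 h A 54 genes passed, without 8 h B 22, and without either 48 h array 27. Within the B arrays the medians were 1.38 for DNA replication, 1.28 for mitosis, 2.96 for tubulins, 1.75 for heat shock proteins, 1.12 for ribosomal proteins, 1.30 for oxidative phosphorylation, 1.42 for the proteasome, 1.14 for luminal markers, -0.36 for markers of other lines, -0.25 for matrix and adhesion and -0.24 for NF-kB and cytokines. With the batch as a block, control B is again the only baseline, and the p-values hold no difference between control arrays. The medians of that fit were -0.25 for matrix and adhesion, -0.31 for markers of other lines and 1.0 for glycolysis.

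The changes at 8 h and at 48 h relative to the arrays labelled control were alike across genes (r = 0.87, rho 0.85, same sign in 84.0%), and both use the same 2 control arrays. Unchanged groups set against shared controls gave a simulated r of 0.498 ± 0.015 (SD over 100 simulations) and the same sign in 66.7%. The covariance was 0.669 against a simulated 0.104, a difference of 0.566. With 8 h set against control A and 48 h against control B r was 0.54, and with the controls exchanged 0.60, each from a single control array. At an unadjusted p under 0.05 in both comparisons, 178 genes were higher in both and 162 lower in both, against 39.8 and 26.4 for independent lists and 28.8 in total with unchanged groups. The simulated arrays varied independently, whereas the 8 h and 48 h arrays share batches, which would raise the simulated values. They also held no profile of cells against the reference. The paclitaxel arrays share such a profile, which control A lacks and control B carries at most in part. It therefore enters both changes, also with the controls split. How much of the likeness exceeds these effects was not measured, so it does not show that the responses to paclitaxel were alike.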

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

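The explanations in this part, and which values were to test them, were chosen after the results were seen. The estimated correlation, fry and the fits without single arrays had themselves been fixed in advance as alternatives. The gene lists themselves and the comparison of 48 h with 8 h were fixed before the data were examined.

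The time points differed in 3 gene lists by camera at its preset correlation, and in none with an estimated correlation or with fry. The median log2 change from 8 h to 48 h was 0.48 for p53 targets, -0.42 for mitosis and -0.55 for DNA replication. Wider log ratios on the 48 h arrays are argued against as the whole cause, since after every array was scaled to the same spread all 3 lists still passed with the same sign (highest camera adjusted p = 0.00113). Their medians were then smaller in size, at 0.28 for p53 targets, -0.39 for mitosis and -0.44 for DNA replication. A constant difference between the batches cancels from the change, because each batch holds 1 array per time, but an effect that differs by batch stays open: the smallest median within a batch was -0.22, and the same sign in both batches decides little for lists picked by their mean change. A chance difference between cultures in genes that vary together stays open, because there were 2 arrays per time. With an estimated correlation the lowest camera adjusted p of the 3 lists was 0.873. That test had few residual degrees of freedom and passed no list in any comparison, so its outcome decides little. A response of the cells to longer paclitaxel exposure is the biological explanation that the design offers, and it stays a hypothesis that is confounded with time in culture.

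Control A lacked the profile shared by the 4 paclitaxel arrays, and control B carried it at most in part. With the paclitaxel arrays control B correlated at r from 0.03 to 0.33 and at rho from -0.11 to 0.20. A response of one kind of cell to paclitaxel would leave the control arrays alike, and they correlated at 0.034 across genes, so it is argued against as the whole cause for control A. That array had a narrow spread (SD 0.26) and correlated between -0.05 and 0.03 with every other array. Its correlation with control B therefore cannot decide whether control B differs from the paclitaxel arrays through treatment. Rows out of register are argued against on control B, where repeated clones correlated at 0.80, and a uniform offset of rows on control A, where no offset gave a correlation above 0.0395 with any paclitaxel array. RNA of another source on control B may account for its profile, since its luminal minus other-line median was 1.04, below all paclitaxel arrays, and nearly the same RNA in both channels of control A may account for that array, where the same value was 0.0056. The treatment effect relative to untreated cells cannot be separated from such a difference with these arrays.

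The genes called at 48 h against the arrays labelled control include 7 of 19 markers of other cell lines. Different RNA on the arrays labelled control may account for part of these calls, since the markers of other lines differed at 48 h against control with camera adjusted p = 0.000776 and did not pass between 48 h and 8 h (0.150). The first did not hold with an estimated correlation (0.920), and the second passed without 8 h B (0.0451) or without 48 h A (0.0311), so this test is weak. A treatment effect on the other called genes stays open as the biological explanation, and it was not tested apart from this.

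Rows without a single gene symbol, which the comparisons do not use, also held a signal relative to the arrays labelled control. Of 1612 such rows with values on all 6 arrays, 109 passed at 48 h against control, 26 higher and 83 lower, a share of 6.76% against 8.06% of named genes.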

How the results depend on the processing

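Across the alternative fits, no named gene that passed in either fit changed sign, while genes past in neither, such as MDM2 and BCL2 at 48 h against control, did. At 48 h against control 1588 gene values kept their side of the threshold, 168 gained it and 295 lost it. In the other comparisons no gene had passed in the main fit. There 83 gene values gained the threshold at 8 h against control and 31 at 48 h against 8 h. Of the list values, 11 gained and 11 lost the threshold at 48 h against control, 6 gained and 8 lost it at 8 h against control, and 20 gained and 0 lost it at 48 h against 8 h. For 48 h against 8 h, no alternative fit ended the calls of p53 targets, mitosis or DNA replication by camera at its preset correlation, while an estimated correlation and fry ended all of them. The luminal breast markers reversed under scale normalization, with a median of -0.0665 (camera adjusted p = 0.0471) against 0.12, and the cause was not tested. Scale normalization, array weights, the batch as a block and the letter with 2 groups were chosen after seeing the data.

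For 48 h against control, 220 genes passed. The count was 494 at adjusted p under 0.10, 220 with at least a 1.5-fold change, 17 with quantile normalization (12 higher, 70.6%, against 43.2% of the 220), 0 with scale normalization and 27 with array weights. It was 350 rows (261 genes) with each row tested, 131 genes with at least 1 array per group and 349 with only the 2 groups fitted. The count ran from 0 to 470 on leaving out 1 array, where the lone array is assumed to vary like the other groups, and it was 1608 with the batch as a block. For 8 h against control, 0 genes passed, with 35 at adjusted p under 0.10, 15 with quantile normalization, 27 with only the 2 groups, 0 to 54 on leaving out 1 array and 1300 with the batch as a block. For 48 h against 8 h, 0 genes passed, 0 to 5 on leaving out 1 array and 454 with the batch as a block. With the batch as a block, both comparisons with control rest on control B alone, so their counts hold no spread between control arrays. The cause of these moves was not tested.

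Of the 11, 7 and 3 lists past at 8 h against control, 48 h against control and 48 h against 8 h, 0, 0 and 0 passed with an estimated correlation and 0, 0 and 0 with fry. With fry in either direction 8 passed at 8 h against control, 12 at 48 h against control and 0 at 48 h against 8 h. Each row tested gave 12, 11 and 6 in the same order. At 48 h against 8 h quantile normalization gave 6 and scale normalization 7. Leaving out 1 array gave 7 to 12, 6 to 8 and 3 to 8. The correlation of the 8 h and 48 h changes was 0.868, and 0.542 and 0.598 with the 2 controls split.

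The labels do not say that the letters A and B pair the arrays, and there are only 2 such sets of arrays. With the letter as a replicate block, 0, 245 and 0 genes passed at 8 h against control, 48 h against control and 48 h against 8 h, with 198 of the 245 among the 220, and the NF-kB and cytokines list did not pass at 48 h against control (camera adjusted p = 0.0784). With only the 2 groups fitted as well, 119, 107 and 454 passed. The B minus A deviations correlated across genes at 0.708 between 8 h and 48 h, at -0.219 between control and 8 h and at -0.171 between control and 48 h. Signal over background was not in the values used, so what low signal limits was not measured.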

Other observations

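The genes in this part were chosen after their values were seen, and the fit with the batch as a block after the data were seen. Of the histone list 4 genes were measured, too few for a test of the list. H4C8 stood at log2 ratios of 1.13 and 2.06 on the 8 h arrays and 2.75 and 4.03 on the 48 h arrays. H2BC21 stood at -0.04 and 0.20 at 8 h and at 1.81 and 2.39 at 48 h. H1-2 changed from 8 h to 48 h by 0.69 on the A arrays and 2.06 on the B arrays, and H3C4 by 0.37 and 0.09. None of these passed between 48 h and 8 h in the main test (limma adjusted p from 0.786 to 0.959), and with the batch as a block H4C8 (adjusted p = 1.4e-09), H2BC21 (adjusted p = 4.33e-12) and H1-2 (adjusted p = 7.51e-06) did. At 48 h against the arrays labelled control, H4C8 and H2BC21 passed in the main test (adjusted p = 0.0266 for each). Histone clones can bind transcripts of related genes, and the rows of H2BC21 disagreed in size.

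Immediate early genes had a median change of 0.46 from 8 h to 48 h, with 12 of 14 positive (camera adjusted p = 0.0850). The list passed with quantile normalization (0.0133), each row tested (0.0163), the median over rows (0.0368) and scale normalization (0.00401), and did not pass with an estimated correlation (0.873) or with fry (0.860). EGR1, a growth-induced transcription factor, changed by 1.47 on the A arrays and 2.15 on the B arrays and JUNB by 0.62 and 1.08, while CCN2 changed by -1.46 and -1.71. SLC2A1, the glucose transporter GLUT1, changed by 0.93 and 1.32, and PSAP, the precursor of the saposins of the lysosome, by 1.16 and 1.32. The long noncoding RNA NEAT1, a p53-responsive component of paraspeckles, changed by 1.29 and 2.07.

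The 8 h profile of one batch was only weakly related across genes to the change from 8 h to 48 h in the other batch (r = 0.105 for 8 h A with the change on B and 0.104 for 8 h B with the change on A).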
